A study of Gallus gallus with 9 samples.

How the data were processed

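Small RNA was sequenced from CD3-negative, 28.4-positive intraepithelial natural killer (IEL-NK) cells enriched from the duodenum of specific-pathogen-free chickens. Per the labels the infected groups received very virulent IBDV (strain UPM0081), total RNA was extracted with TRIzol, libraries were made with the TruSeq small RNA kit, and sequencing was on a MiSeq. There were 9 samples, 3 uninfected controls, 3 at day 1 and 3 at day 3. The labels do not say whether the samples of a group came from separate birds, and give no day for the controls, so whether time was matched is open. The p-values measure the spread between these samples, some or all of which may be technical. The chi-square of counts per degree of freedom was lowest, 1.53, between day 1 replicates 1 and 3. It was 1.77 between day 3 replicates 2 and 3, and highest, 23.8, between control replicates 2 and 3. The lowest values were not far above counting error, so how much variation between birds the p-values hold is unknown.

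The authors deposited 1 table of raw counts per mature miRNA name for each sample, aligned to galGal4, and the aligner, the counter and the miRNA annotation are not given in the sources used here. The authors' deposited tables for day 1 and day 3 hold a scaled signal per sample for miRNAs, snoRNAs and small nuclear RNAs (snRNAs). They were tested on the files: multiplied by 1 factor per column, the signal gave whole reads in 100% of 299 and 277 features (tolerance 0.01), and in 11 of 12 columns that factor equalled the median-ratio size factor (tolerance 0.1%), with a difference of 0.401% in the other. The log2 fold changes in the authors' deposited tables are those of each day over control, with their standard errors, and are smaller in size than the log2 ratio of group means for features with low counts. Each p-value and adjusted p-value in the authors' deposited tables was computed by the authors with a tool that the file headers do not name, though the column names are those DESeq2 writes. Whole reads of 113 snoRNAs and 2 snRNAs were recovered from these tables for all 9 samples.

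Counts of 659 miRNA names with at least 1 count were tested after edgeR's filterByExpr (minimum count 10, minimum total 15), which left 112 miRNAs holding at least 99.8% of the counts of every sample. Of all names 17 were predicted miRNAs and 5 joined 2 names. Libraries were scaled by TMM and fitted with edgeR's quasi-likelihood model over all 9 samples (6 residual degrees of freedom, common biological coefficient of variation 8.85%). The comparisons were day 1 against control, day 3 against control, day 3 against day 1 and any difference between the 3 groups. P-values were adjusted by Benjamini-Hochberg within a comparison, with 0.05 as the threshold, and adjusted p-values in the text come from edgeR unless another tool is named. The SE of a fitted log2 fold change is approximate, namely its absolute value divided by the square root of the quasi-likelihood F statistic. CPM are TMM-scaled counts except in the detection limits, which use library totals. Ratios of low counts have exact binomial 95% intervals on summed counts. These intervals, the Wilson intervals and the limit for a count of 0 (3 counts) cover counting error only, since reads without molecular identifiers are not independent molecules.

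miRNAs were named in the text by a rule. All called miRNAs of a comparison were named if there were 20 or fewer, and otherwise the 12 with the largest increase and the 12 with the largest decrease among those called. The 4 most abundant tested members of each list, the 10 most abundant miRNAs and the 10 with the smallest adjusted p in each of the authors' tables were named as well. Further list members are named as examples of a count and were chosen after their values were seen. The rule, the 11 lists, the comparisons and most alternatives were fixed before the data were examined.

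The lists were matched by miRNA name. They were lymphocyte and natural killer cell (27 names matched, 10 tested), inflammatory response (16, 11), linked to IBDV replication or response in cell culture (15, 8), miR-17-92 family (18, 9), let-7 family (14, 7), p53-responsive (9, 4), myeloid (2, 2), erythroid and thrombocyte (5, 3), intestinal epithelium (10, 9), smooth muscle and stroma (21, 6) and pancreas and liver (7, 2). Of the tested members 6, 7, 5, 0, 0, 3, 1, 0, 3, 0 and 0, in that order, also belonged to another list. Lists were tested with limma's camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, each adjusted over 11 lists. Summed shares of counts and library measures were compared over the 3 groups by exact permutation of the F statistic over all assignments of samples to groups, where the smallest possible p is 0.00357. A comparison of 3 samples with 3 cannot give a two-sided permutation p under 0.1.

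Genomic positions are the galGal4 coordinates of the authors' deposited tables (108 of the tested miRNAs). Gene names, neighbours and host genes came from the GRCg7b annotation, to which 110 tested miRNAs were matched. The correlation and covariance of the changes on the 2 days were set against 100 simulated pairs of unchanged groups that shared the controls. Alternatives were other scalings, filters and tests, thinning to the smallest library, replicate number as a block, leaving out each sample, leaving out the most abundant miRNA, and, added after seeing the data, a joint fit with the recovered snoRNA and snRNA reads, scaling to those reads, leaving out the epithelial list and adding miR-222a and miR-222b to the inflammatory list. On data simulated from the day 1 comparison (20 simulations) the pipeline called 58.1% of 1.5-fold, 83.1% of 2-fold and 95.3% of 4-fold changes among tested miRNAs, and 4.64% of its calls were unchanged miRNAs. With no effect simulated, 0.0912% of miRNAs were called and 3.64% of lists had a camera p under 0.05. In all simulations miR-215-5p was kept unchanged, and simulated increases and decreases were equally likely. The rates therefore do not cover the dependence on scaling seen at day 1. Each miRNA was simulated independently, so the rate for lists does not cover correlation between the members of a list. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9, with random seed 11. Raw reads were not analysed here.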

Results

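Mature miRNA counts were available from 9 samples of chicken (Gallus gallus) IEL-NK cells, natural killer cells that lie among the epithelial cells of the gut lining, enriched from the duodenum as CD3-negative, 28.4-positive cells. The comparison asked how miRNA levels in samples enriched for these cells differed after infection with very virulent infectious bursal disease virus (IBDV). IBDV is a double-stranded RNA virus whose main target is the B cell of the bursa of Fabricius. The samples formed 3 groups of 3, namely uninfected controls, day 1 after infection and day 3 after infection. Total miRNA counts per sample were 278775, 370664 and 330049 in the controls, 183316, 198996 and 174527 at day 1, and 516613, 383853 and 325238 at day 3. Depth therefore differed between the groups (exact permutation test over the 3 groups, p = 0.0107, adjusted p = 0.0286 over 4 library measures). A count of 0 allowed a level of up to 5.81 CPM (counts scaled to library size) in the deepest sample and up to 17.2 CPM in the shallowest, from counting error alone. Between 254 and 340 miRNA names had at least 1 count in a sample.

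The libraries were dominated by miRNAs of the intestinal epithelium. miR-215-5p alone took 65.8% ± 2.79 (SD, n = 3) of the counts in controls, 56.1% ± 1.80 at day 1 and 55.8% ± 0.666 at day 3, and miR-194, transcribed next to it, took 12.3% ± 1.67, 14.0% ± 1.74 and 13.0% ± 0.526. miR-21-5p, a miRNA of activated and inflamed tissue, took 6.92% ± 1.09, 9.36% ± 0.451 and 16.0% ± 0.258. The next in abundance were miR-200b-3p (3.11% of counts over all samples), miR-200a-3p (2.87%), miR-148a-3p (1.60%), miR-30d (0.774%), miR-7446-3p (0.636%), miR-146c-5p (0.605%) and miR-26a-5p (0.560%). These 10 miRNAs held between 91.4% and 94.7% of the counts of each sample. The share of miR-215-5p differed between the 3 groups (exact permutation test, p = 0.0357, adjusted p = 0.0357). In the most extreme single samples it was 54.1% (95% Wilson interval 53.9 to 54.4%) and 67.6% (67.4 to 67.7%), so counting error was small beside the spread between samples.

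**Figure D1:**
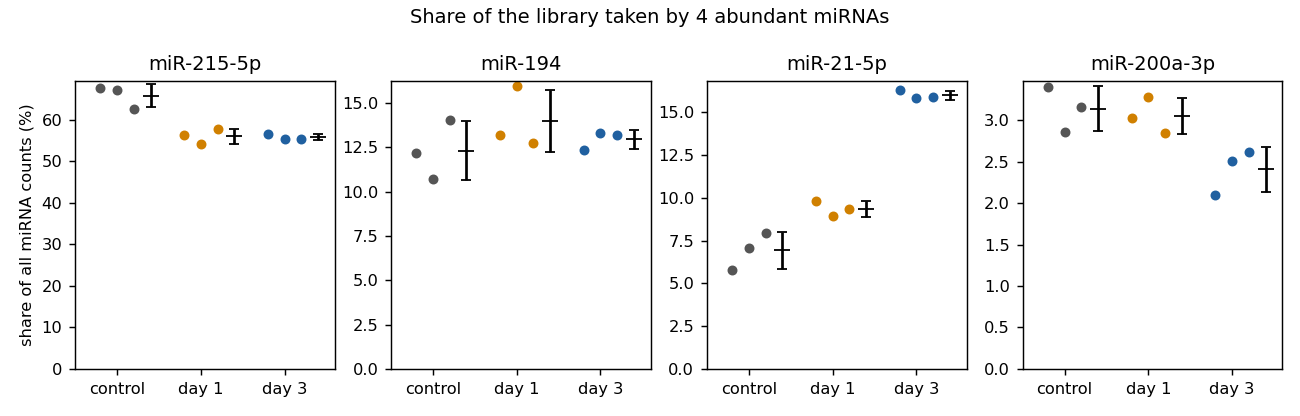
Share of all miRNA counts (%, linear axis from 0) taken by miR-215-5p, miR-194, miR-21-5p and miR-200a-3p in each of the 9 samples, coloured by group. The black bar beside each group is its mean and the whiskers its SD (n = 3). The share of miR-215-5p was 65.8% in controls, 56.1% at day 1 and 55.8% at day 3, and that of miR-21-5p was 6.92%, 9.36% and 16.0%.

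Markers of other cell types were counted in every group, and their shares differed between the groups. The changes given below are therefore those of the enriched samples and cannot be assigned to natural killer cells. The summed epithelial list held 84.2% ± 1.52 (SD, n = 3) of the counts in controls, 77.8% ± 0.470 at day 1 and 74.3% ± 0.217 at day 3, while the lymphocyte and natural killer cell list held 0.844% ± 0.0198, 1.19% ± 0.0800 and 0.920% ± 0.0379. The erythroid and thrombocyte list held 0.0161% ± 0.00385, 0.0869% ± 0.00647 and 0.0167% ± 0.00420, and the pancreas and liver list 0.00520% ± 0.000225, 0.0316% ± 0.00217 and 0.00415% ± 0.000467. The smooth muscle and stroma list held 0.0901% ± 0.00287, 0.138% ± 0.00457 and 0.151% ± 0.0131, and the myeloid list 0.0822% ± 0.00842, 0.122% ± 0.00497 and 0.105% ± 0.00562. The remaining lists held 7.72%, 10.6% and 17.0% (inflammatory response), 7.07%, 9.54% and 16.1% (linked to IBDV), 0.464%, 0.786% and 0.430% (miR-17-92), 0.921%, 1.98% and 1.26% (let-7) and 78.2%, 70.1% and 68.8% (p53-responsive). All 11 shares differed between the 3 groups in exact permutation tests, with adjusted p from 0.00437 to 0.0357. The inflammatory and IBDV-linked sums were mostly miR-21-5p, which alone held 6.92%, 9.36% and 16.0%. The p53-responsive and epithelial sums were mostly miR-215-5p and miR-194. Shares of lists with the same main members are therefore not separate results. The myeloid sum was mostly miR-147. Its other member, miR-223, was lower than in controls by edgeR on both days (log2 −0.94 at day 1 and −1.58 at day 3), against the higher share. Within the lymphocyte and natural killer cell share, miR-146c-5p alone held 0.447%, 0.748% and 0.622%, and the inflammatory list holds it too. With edgeR no tested member of the lymphocyte list was called higher at day 1, and 2 were lower. A share also depends on every other miRNA. With TMM scaling the lymphocyte, inflammatory, IBDV-linked, myeloid and stromal sums were lower at day 1 than in controls, not higher.

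At day 1 after infection the largest increase was that of miR-217-5p, a miRNA best known from the pancreas, with 4 counts over the 3 controls and 106 over the 3 day 1 samples (ratio of scaled counts 28.4, exact 95% interval 10.8 to 106). miR-451, the main miRNA of red blood cells, rose 3.81-fold (log2 1.93, SE 0.211, adjusted p = 2.91e-08), from 122 ± 36.3 to 458 ± 46.4 CPM (SD, n = 3). miR-22-3p fell by 1.20 on the log2 scale (SE 0.103, adjusted p = 3.14e-10), miR-7446-3p by 1.23 (SE 0.103, adjusted p = 2.97e-10) and miR-215-5p by 0.95 (SE 0.0856, adjusted p = 7.17e-10), all without overlap between the samples of the groups. Of 112 miRNAs tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 53 differed from controls at an adjusted p under 0.05, 29 higher and 24 lower, and 13 were at least 2-fold higher and 4 at least 2-fold lower. For 51 of the 53 the samples of the groups did not overlap, and for 57 of all 112, where chance gives 10%.

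The 12 largest increases at day 1 were, after miR-217-5p, those of miR-2188-5p (log2 2.19, SE 0.374), miR-451, miR-10a-5p (1.54, SE 0.295), miR-17-3p (1.42, SE 0.581), miR-222b-5p (1.38, SE 0.308), miR-3607-3p (1.30, SE 0.318), miR-126-3p (1.26, SE 0.284), miR-144-3p (1.25, SE 0.366), miR-222a (1.13, SE 0.146), miR-6651-5p (1.09, SE 0.308) and miR-6601-3p (1.09, SE 0.398). The 12 largest decreases were led by miR-21-3p (log2 −2.05, SE 0.450), the minor arm of the miR-21 hairpin, and after miR-7446-3p and miR-22-3p came miR-32-5p (−1.05, SE 0.226), miR-146b-5p (−0.95, SE 0.116), miR-215-5p, miR-223 (−0.94, SE 0.335), miR-142-5p (−0.82, SE 0.136), miR-200a-3p (−0.75, SE 0.0987), miR-140-3p (−0.71, SE 0.0930), miR-1692 (−0.71, SE 0.181) and miR-215-3p (−0.65, SE 0.176). Some of these rested on few counts. miR-2188-5p had 15 counts over the controls and 65 at day 1 (ratio 4.65, exact 95% interval 2.62 to 8.77), miR-17-3p 7 and 18 (2.76, 1.10 to 7.81) and miR-21-3p 41 and 9 (0.235, 0.101 to 0.492). Calls lost on leaving out 1 sample were those of miR-17-3p (control replicate 1 or any day 1 replicate), miR-6601-3p (control replicate 1 or 2, day 1 replicate 1 or 3) and miR-223 (control replicate 2, day 1 replicate 1 or 3).

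Among the fixed lists, all 3 tested erythroid and thrombocyte miRNAs rose at day 1 (miR-451, miR-144-3p and the endothelial and thrombocyte miR-126-3p). In the pancreas and liver list miR-217-5p rose and the liver miRNA miR-122-5p did not pass the test (log2 −0.49, SE 0.321). In the intestinal epithelium list 4 of 9 fell (miR-215-5p, miR-215-3p, miR-200a-3p and miR-194, the last by 0.52 on the log2 scale, SE 0.0946), 1 rose (miR-375, 0.45) and 4 did not pass, among them miR-200b-3p (−0.04, SE 0.0866). Of 4 p53-responsive miRNAs 3 fell, namely the miR-215 arms and miR-194, which the epithelial list also holds, and miR-34a-5p did not pass (−0.41, SE 0.340). Of 7 let-7 miRNAs 5 rose, among them let-7k-5p (0.84), let-7i (0.47, SE 0.0979), let-7g-5p (0.37, SE 0.103) and let-7f-5p (0.32, SE 0.100), while the joined let-7j-5p and let-7a-5p entry did not pass (0.31, SE 0.133). The let-7 count was 3 without control replicate 3 and 1 with snoRNA scaling, and with total counts 1 epithelial and 1 p53-responsive miRNA were lower, both miR-215-5p, and 5 epithelial ones higher.

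Of the lymphocyte and natural killer cell list, 2 of 10 fell (miR-146b-5p and miR-142-5p) and none rose. miR-142-3p (−0.08, SE 0.146), miR-146c-5p (0.02, SE 0.102) and miR-155 (0.23) did not pass. Of 11 inflammatory miRNAs 2 rose, miR-221-3p (0.78, SE 0.143) and miR-221-5p (0.97), and 3 fell, miR-146b-5p and both arms of miR-21 (miR-21-5p by 0.28 on the log2 scale, SE 0.0920, with overlapping samples). Of 8 miRNAs linked to IBDV replication or response in cell culture 4 fell, namely the miR-21 arms, miR-142-5p and miR-27b-3p (−0.53, SE 0.146), and 4 did not pass, among them miR-16-5p (0.02, SE 0.154). In the miR-17-92 family 3 of 9 rose (miR-17-3p, miR-20b-5p by 0.65 with SE 0.152, and miR-106-3p), and miR-20a-5p (0.22, SE 0.136), miR-92-3p (−0.11, SE 0.113) and miR-19b-3p (−0.11, SE 0.161) did not pass. In the smooth muscle and stroma list miR-99a-5p (0.91, SE 0.334) and miR-199-5p (1.02) rose, miR-100-5p fell by 0.33 (SE 0.117), and miR-199-3p (0.59, SE 0.315) and miR-1a-3p (0.31, SE 0.339) did not pass. Of the 2 myeloid miRNAs miR-223 fell and miR-147 did not pass (−0.10, SE 0.119). Of the abundant miRNAs not yet given, miR-26a-5p fell by 0.32 (SE 0.111) and miR-30d by 0.23 (SE 0.0923) on the log2 scale, miR-101-3p fell by 0.61 (SE 0.0953), and miR-148a-3p did not pass (−0.07, SE 0.102). Leaving out 1 sample ended the calls of miR-26a-5p (control replicate 2, day 1 replicate 1 or 3), miR-30d (any sample but control replicate 1 or 3) and miR-99a-5p (control replicate 3 or day 1 replicate 2). With total counts 0 lymphocyte miRNAs were lower and 7 higher, 1 inflammatory miRNA was lower and 6 were higher, 1 IBDV-linked miRNA was lower and 3 were higher, and 7 of the miR-17-92 family and 6 of the stromal list were higher. The miR-17-92 count was 1 without control replicate 1 or any 1 day 1 replicate and 0 with snoRNA scaling (3 lower), and the count of higher stromal miRNAs was 0 without day 1 replicate 2 and 1 without any 1 control or day 3 replicate 2. The call of miR-100-5p was lost without control replicate 2, day 1 replicate 1, day 1 replicate 2 or day 3 replicate 2.

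Over the members of all lists at day 1, counting a miRNA once for each list that holds it, 35 of 71 passed when adjusted over all miRNAs tested and 34 when adjusted over the list alone. In the miR-17-92 family 1 rose when adjusted over the list alone, and in the let-7 family 6. As sets, 0 of 11 lists differed from the other miRNAs by limma's camera (4 at an unadjusted p under 0.05, lowest adjusted p = 0.0544), 0 did so with an estimated correlation (lowest adjusted p = 0.309), and fry, which does not compare with other miRNAs, called 8. The inflammatory list had a median of 0.02 but a mean of −0.13 and a downward test direction. The count at day 1 depended on the scaling, and the TMM factors averaged 0.826 in controls, 1.35 at day 1 and 0.896 at day 3. With total counts alone the median log2 change moved by 0.71 and 73 miRNAs were higher and 4 lower, against 21 higher and 29 lower with upper quartile scaling, 21 and 30 when fitted together with the recovered snoRNA reads, and 15 and 46 when scaled to those reads. miR-217-5p, miR-451, miR-2188-5p, miR-222a, miR-22-3p, miR-7446-3p and miR-215-5p were called in the same direction under every alternative that tested them. With total counts, though, miR-215-5p fell by only 0.23, miR-22-3p fell by only 0.49 and miR-7446-3p fell by only 0.52 on the log2 scale. Also with total counts, miR-21-5p (log2 0.44), miR-26a-5p, miR-30d and miR-100-5p were called higher at day 1. The values of miR-194 (0.18), miR-215-3p, miR-27b-3p, miR-101-3p and miR-1692 turned positive there but were not called. The call of miR-223 was lost without control replicate 2, day 1 replicate 1 or day 1 replicate 3, and that of miR-21-5p without control replicate 2, day 1 replicate 2 or day 3 replicate 2.

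**Figure D2:**
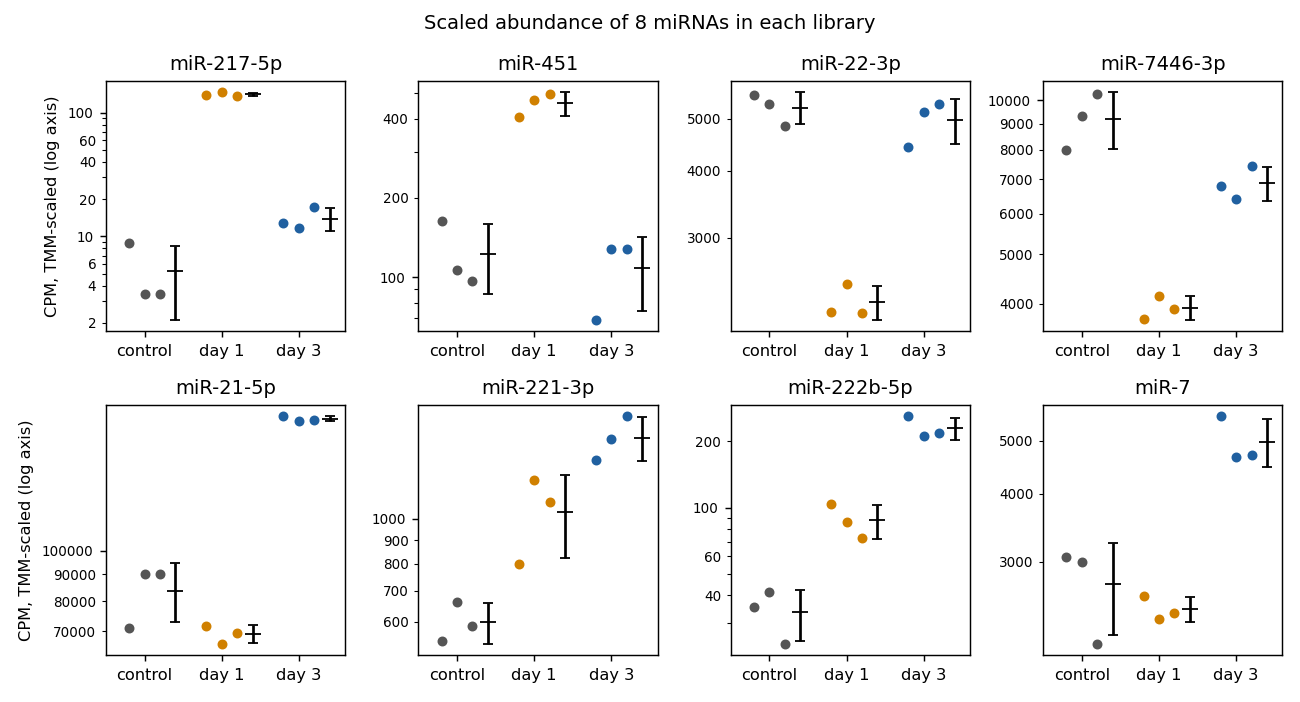
TMM-scaled abundance (CPM, log axis) of 8 miRNAs in each of the 9 samples, coloured by group, with the group mean and SD (n = 3) in black beside the points. miR-217-5p and miR-451 were higher at day 1, miR-22-3p and miR-7446-3p lower at day 1, and miR-21-5p, miR-221-3p, miR-222b-5p and miR-7 higher at day 3 than in controls. With total counts in place of TMM these directions held for all 8.

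At day 3 after infection the miR-221 and miR-222 miRNAs and miR-21-5p stood above controls. miR-222b-5p rose 6.84-fold (edgeR, log2 2.77, SE 0.246, adjusted p = 9.39e-10), from 33.6 ± 8.70 to 229 ± 27.0 CPM (SD, n = 3). miR-21-5p, the most abundant miRNA among those called higher, rose 2.13-fold (log2 1.09, SE 0.0929, adjusted p = 7.58e-10), miR-222a 2.49-fold (1.32, SE 0.141) and miR-221-3p 2.48-fold (1.31, SE 0.138). miR-223, a miRNA of granulocytes and monocytes, fell by 1.58 on the log2 scale (SE 0.337, adjusted p = 0.000574), and miR-30a-5p by 1.10 (SE 0.120, adjusted p = 2.63e-08). By the same edgeR test 42 of 112 miRNAs differed from controls, 25 higher and 17 lower, with 7 at least 2-fold higher and 5 at least 2-fold lower. The samples of the groups did not overlap for 37 of the 42, and for 50 of all 112.

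The other large increases at day 3 were those of miR-1b-3p (log2 2.20, SE 0.446), a muscle miRNA with 8 counts over the controls and 52 at day 3 (ratio 4.78, exact 95% interval 2.26 to 11.7), miR-9-5p (1.06, SE 0.336), the p53 target miR-34a-5p (1.01, SE 0.259), miR-3607-3p (0.99, SE 0.312), miR-6651-5p (0.94, SE 0.295), miR-99a-5p (0.91, SE 0.313), miR-7 (0.87, SE 0.117) and miR-221-5p (0.86, SE 0.234). miR-2954, encoded on the Z chromosome, rose by 0.74 (SE 0.108, adjusted p = 4.41e-06). The other large decreases were those of miR-148a-5p (−1.22, SE 0.481), with 26 counts over the controls and 15 at day 3 (ratio 0.424, 0.209 to 0.831), miR-3528 (−1.06, SE 0.401), miR-122-5p (−1.03, SE 0.320), miR-1559-5p (−0.89, SE 0.273), miR-146a-5p (−0.81, SE 0.230), miR-146b-5p (−0.80, SE 0.113), miR-32-5p (−0.66, SE 0.203), miR-30b-5p (−0.64, SE 0.204), miR-142-5p (−0.62, SE 0.129) and miR-200a-3p (−0.50, SE 0.0982). miR-215-5p fell by 0.36 (SE 0.0849) and miR-7446-3p by 0.42 (SE 0.100). Among the decreases, leaving out 1 sample ended the calls of miR-148a-5p (control replicate 1 or 2, or any day 3 replicate), miR-3528 (control replicate 1 or 2, day 3 replicate 1 or 3), miR-122-5p (day 3 replicate 1), miR-1559-5p (day 3 replicate 3), miR-32-5p (control replicate 3 or day 3 replicate 2) and miR-30b-5p (control replicate 1, day 3 replicate 1 or 2). Among the increases it ended those of miR-9-5p (control replicate 2 or day 3 replicate 1), miR-3607-3p (control replicate 3), miR-6651-5p (control replicate 2, day 3 replicate 1 or 3), miR-99a-5p (control replicate 3 or day 3 replicate 1) and miR-221-5p (day 3 replicate 1).

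By list, 7 of 11 inflammatory miRNAs rose at day 3 (miR-21-5p, both arms of miR-221, miR-9-5p, miR-125b-5p by 0.85, miR-146c-5p by 0.35 with SE 0.102, and miR-147) and 2 fell (miR-146a-5p and miR-146b-5p, miRNAs known to dampen innate immune signalling). Without day 3 replicate 1 the count of 7 was 4, with miR-9-5p, miR-221-5p and miR-146c-5p lost, and the call of miR-147 was lost without control replicate 1, control replicate 3, day 1 replicate 3 or day 3 replicate 3. By the fixed matching rule miR-222a and miR-222b-5p did not belong to that list. Of 10 lymphocyte and natural killer cell miRNAs 3 fell (miR-142-5p, miR-146a-5p and miR-146b-5p), 1 rose (miR-146c-5p), and miR-142-3p did not pass (−0.17, SE 0.141). Of 8 IBDV-linked miRNAs miR-21-5p rose and miR-142-5p fell, while miR-27b-3p (0.03, SE 0.134) and miR-16-5p (−0.22, SE 0.150) did not pass. Of the let-7 family 4 of 7 rose, among them let-7g-5p (0.54, SE 0.102), the let-7j-5p and let-7a-5p entry (0.44, SE 0.130) and let-7f-5p (0.32, SE 0.0995), and let-7i did not pass (0.03, SE 0.0977). That count was 1 without control replicate 3 and 2 without day 3 replicate 3. None of the 9 miR-17-92 miRNAs passed, among them miR-92-3p (−0.23, SE 0.112), miR-20a-5p (−0.17, SE 0.135), miR-19b-3p (−0.33, SE 0.157) and miR-20b-5p (−0.26, SE 0.157). None of the 3 erythroid and thrombocyte miRNAs passed, with miR-451 at −0.19 (SE 0.251), miR-126-3p at 0.53 (SE 0.294) and miR-144-3p at −1.22 (SE 0.493).

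Of 9 epithelial miRNAs at day 3, miR-215-5p and miR-200a-3p fell, and miR-194 (−0.04, SE 0.0942) and miR-200b-3p (0.00, SE 0.0864) did not pass. Of 4 p53-responsive miRNAs miR-34a-5p rose, miR-215-5p fell, and miR-194 and miR-215-3p (−0.12, SE 0.158) did not pass, so that the list's median was −0.08 and its mean 0.12. In the smooth muscle and stroma list 3 of 6 rose (miR-1b-3p, miR-99a-5p and miR-100-5p by 0.66 with SE 0.109), and miR-1a-3p (0.04, SE 0.327) and miR-199-3p (−0.27, SE 0.330) did not pass. Of the myeloid pair miR-147 rose by 0.30 (SE 0.114) and miR-223 fell. Of the pancreas and liver pair miR-122-5p fell and miR-217-5p did not pass (15 counts at day 3 against 4, ratio 2.76, 0.879 to 11.4). The median of the IBDV-linked list was −0.21 and its camera direction down, while fry gave up. Over all lists 29 of 71 members passed when adjusted over all miRNAs and 30 when adjusted over the list alone, the difference being miR-217-5p. By camera 0 of 11 lists differed (1 at an unadjusted p under 0.05, lowest adjusted p = 0.242; with an estimated correlation 0, lowest adjusted p = 0.509), and fry called 4. Of the abundant miRNAs miR-30d fell by 0.25 (SE 0.0919), a call lost without control replicate 2, day 1 replicate 1 or any day 3 replicate, and miR-26a-5p (0.02, SE 0.109) and miR-148a-3p (−0.20, SE 0.102) did not pass. The split of higher against lower calls was 31 and 10 with total counts (median shift 0.12), 16 and 36 with upper quartile scaling (median shift −0.19), 20 and 26 when fitted with the snoRNA reads and 19 and 23 when scaled to them. Without day 3 replicate 1 the count of miRNAs called fell to 27.

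**Figure D3:**
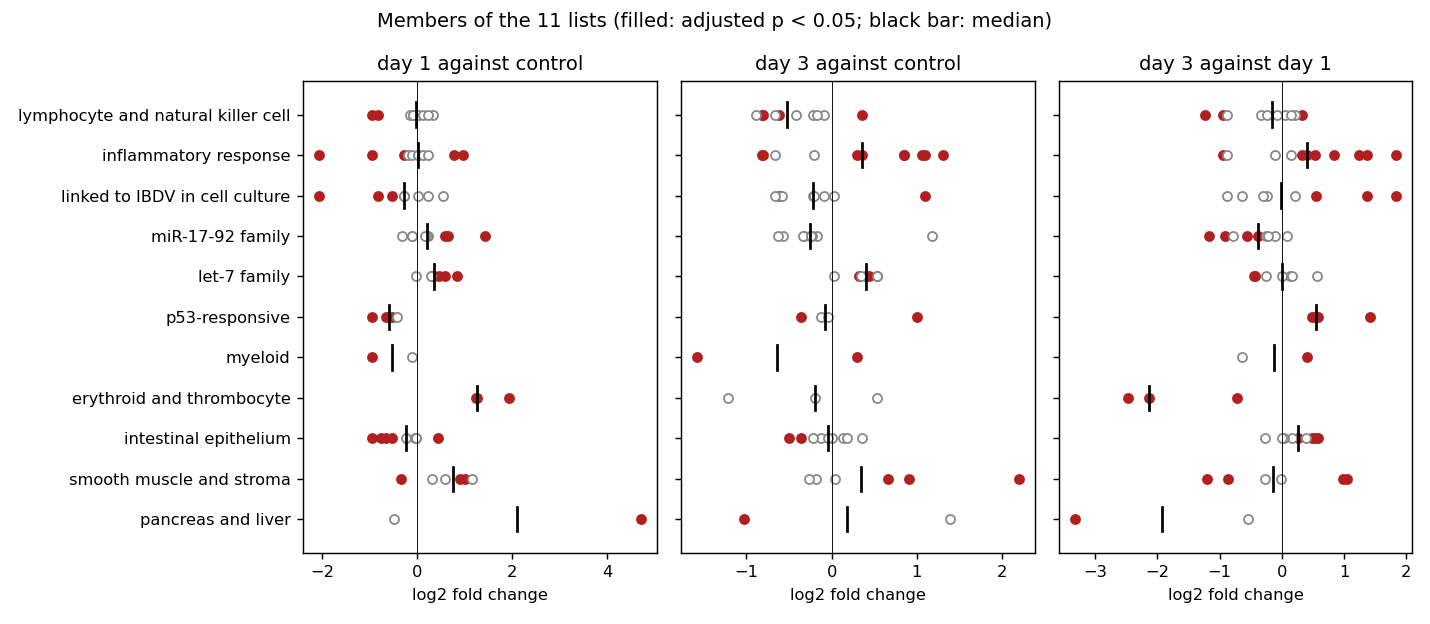
Log2 fold changes of the tested members of the 11 lists in the 3 comparisons. Each circle is 1 miRNA, filled where edgeR's adjusted p was under 0.05, and the black bar is the median of the list. At day 1 all 3 erythroid and thrombocyte miRNAs were higher, and at day 3 7 of 11 inflammatory miRNAs were (4 without day 3 replicate 1). Among the called members the direction at day 1 turned under total counts for miR-194, miR-21-5p, miR-215-3p, miR-27b-3p and miR-100-5p.

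Set directly against day 1, day 3 had lower miR-217-5p, miR-451 and miR-144-3p and higher miR-21-5p and miR-34a-5p. miR-217-5p fell by 3.32 on the log2 scale (SE 0.294, adjusted p = 8.87e-10), miR-451 by 2.13 (SE 0.204, adjusted p = 2.61e-09) and miR-2188-5p by 3.05 (SE 0.392), and miR-21-5p rose 2.58-fold (log2 1.37, SE 0.0935, adjusted p = 5.50e-12). This comparison is also the test of whether the differences from controls differed between the 2 days, since both used the same controls. It called 51 of 112 miRNAs, 29 higher and 22 lower at day 3, with 8 at least 2-fold higher and 9 at least 2-fold lower. The samples of the groups did not overlap for 47 of the 51, and for 60 of all 112.

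The largest increases from day 1 to day 3 were those of miR-21-3p (log2 1.84, SE 0.443; 9 counts at day 1 and 48 at day 3, ratio 3.66, exact 95% interval 1.77 to 8.48), miR-34a-5p (1.42, SE 0.282), miR-222b-5p (1.39, SE 0.204), miR-21-5p, miR-9-5p (1.24, SE 0.353), miR-22-3p (1.13, SE 0.103), miR-1b-3p (1.04, SE 0.375), miR-7 (1.02, SE 0.118), miR-100-5p (0.99, SE 0.112), miR-2954 (0.85, SE 0.110), miR-125b-5p (0.83, SE 0.313) and miR-7446-3p (0.81, SE 0.103). The largest decreases, after those named, were those of miR-144-3p (−2.46, SE 0.408; 47 and 12 counts, ratio 0.175, 0.0845 to 0.335), miR-10a-5p (−1.71, SE 0.282), miR-1416-5p (−1.32, SE 0.510; 26 and 15 counts, ratio 0.396, 0.195 to 0.775), miR-181a-3p (−1.23, SE 0.435), miR-199-5p (−1.20, SE 0.392), miR-106-3p (−1.17, SE 0.242), miR-146a-5p (−0.95, SE 0.229), miR-6516-3p (−0.92, SE 0.289) and miR-20b-5p (−0.91, SE 0.150). Leaving out 1 sample ended the calls of miR-1b-3p (day 1 replicate 3 or day 3 replicate 1), miR-125b-5p (day 1 replicate 1 or 3, day 3 replicate 2 or 3), miR-1416-5p (control replicate 1, day 1 replicate 1 or 3, or any day 3 replicate), miR-181a-3p (day 1 replicate 3, day 3 replicate 2 or 3), miR-199-5p (day 1 replicate 1 or day 3 replicate 1) and miR-6516-3p (day 1 replicate 2 or day 3 replicate 2).

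The erythroid and thrombocyte list was lower at day 3 than at day 1 in all 3 members, among them miR-126-3p (−0.72, SE 0.246), and was the only list that camera called (adjusted p = 0.0249; adjusted p = 0.217 with an estimated correlation). All 4 p53-responsive miRNAs rose, namely miR-34a-5p, miR-215-5p (0.59, SE 0.0851), miR-215-3p (0.53, SE 0.172) and miR-194 (0.48, SE 0.0945). The last 3 lie together on chromosome 3, and their values turned negative with total counts. Of 9 epithelial miRNAs 4 rose, those 3 and miR-200a-3p (0.25, SE 0.0983), and miR-200b-3p did not pass (0.04, SE 0.0865). Of 11 inflammatory miRNAs 7 rose, among them both arms of miR-21, miR-221-3p (0.53, SE 0.131) and miR-146c-5p (0.33, SE 0.102), and miR-146a-5p fell. Of 8 IBDV-linked miRNAs 3 rose, the miR-21 arms and miR-27b-3p (0.55, SE 0.142), with a list median of −0.02 and a mean of 0.24, and miR-142-5p (0.21, SE 0.138) and miR-16-5p (−0.24, SE 0.151) did not pass. Of 10 lymphocyte miRNAs miR-146c-5p rose, miR-146a-5p and miR-181a-3p fell, and miR-146b-5p (0.15, SE 0.117) and miR-142-3p (−0.08, SE 0.143) did not pass. In the miR-17-92 family 4 of 9 fell, miR-106-3p, miR-17-5p, miR-20b-5p and miR-20a-5p (−0.38, SE 0.134), and miR-92-3p (−0.11, SE 0.113) and miR-19b-3p (−0.23, SE 0.160) did not pass. In the let-7 family let-7i (−0.44, SE 0.0969) and let-7k-5p fell, and let-7g-5p (0.17, SE 0.101), let-7f-5p (0.00, SE 0.0991) and the let-7j-5p and let-7a-5p entry (0.14, SE 0.129) did not pass. Calls lost on leaving out 1 sample were those of miR-126-3p (day 1 replicate 2 or 3, day 3 replicate 1 or 2), miR-215-3p (day 1 replicate 1), miR-200a-3p (day 1 replicate 1 or 3, day 3 replicate 2 or 3), miR-146c-5p (day 1 replicate 2 or day 3 replicate 1) and miR-20a-5p (day 1 replicate 1 or 3, day 3 replicate 1).

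In the smooth muscle and stroma list miR-1b-3p and miR-100-5p rose from day 1 to day 3, miR-199-5p and miR-199-3p (−0.86, SE 0.306) fell, and miR-99a-5p (−0.01, SE 0.276) and miR-1a-3p (−0.28, SE 0.317) did not pass. miR-147 rose by 0.40 (SE 0.115) while miR-223 (−0.64, SE 0.397) and miR-122-5p (−0.54, SE 0.352) did not pass. The call of miR-199-3p was lost without day 1 replicate 2, day 3 replicate 1 or day 3 replicate 3. Of the abundant miRNAs miR-26a-5p rose by 0.34 (SE 0.110), a call lost without day 1 replicate 1, day 1 replicate 3, day 3 replicate 2 or day 3 replicate 3, and miR-30d (−0.02, SE 0.0921) and miR-148a-3p (−0.12, SE 0.102) did not pass. Over all lists 37 of 71 members passed when adjusted over all miRNAs and 38 when adjusted over the list alone, and fry called 7 of 11 lists. Adjusted over the list alone, 1 epithelial miRNA was also lower. The myeloid and stromal lists had negative medians (−0.12 and −0.14) and upward camera directions. With total counts the median moved by −0.59 and 8 miRNAs were higher and 75 lower, and with scaling to the snoRNA reads 44 were higher and 10 lower. With total counts 2 inflammatory, 0 epithelial and 1 p53-responsive miRNA were called higher, against 7, 4 and 4 as reported, and 5 inflammatory and 5 epithelial ones lower. Without day 3 replicate 1 the count of lower miR-17-92 miRNAs was 2 and that of lower stromal miRNAs 0. The values of miR-215-5p, miR-215-3p, miR-194, miR-27b-3p, miR-221-3p, miR-200a-3p, miR-146c-5p, miR-147 and miR-26a-5p turned negative with total counts.

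Over all 3 groups together 74 of 112 miRNAs differed (edgeR, adjusted p under 0.05). On both days 11 miRNAs were higher than controls, among them miR-222b-5p, miR-222a, both arms of miR-221, miR-99a-5p and 3 let-7 miRNAs, and 11 were lower, among them miR-215-5p, miR-146b-5p, miR-142-5p, miR-200a-3p, miR-32-5p, miR-223 and 4 miR-30 miRNAs. miR-21-5p and miR-100-5p were lower at day 1 and higher at day 3. With total counts 28 were higher and 2 lower on both days (the latter miR-215-5p and miR-7446-3p) and 1 was opposite (miR-146a-5p), and with snoRNA scaling 6 were higher, 19 lower and 5 opposite. Upper quartile scaling gave 7 higher, 17 lower and 5 opposite, and the joint fit with the snoRNA reads 7, 15 and 4. The count of higher ones was 5 without a low-count filter, 7 with DESeq2 and 7 without day 3 replicate 1. The count of opposite ones was 0 with the stricter filter, with thinning, or without control replicate 2, day 1 replicate 2 or day 3 replicate 2. It was 1 without day 1 replicate 1 and 4 without control replicate 3. Independent lists of these sizes would share 6.47 higher and 3.64 lower miRNAs. Across miRNAs, which are not independent replicates, the changes on the 2 days had a Pearson correlation of 0.430, against a mean of 0.525 (range 0.203 to 0.685) over 100 simulated pairs of unchanged groups that shared the controls, and a covariance of 0.242 against 0.0357, a difference of 0.207. The 3 controls could not be split into parts of 2 or more, so part of the excess overlap may come from the shared controls.

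**Figure D4:**
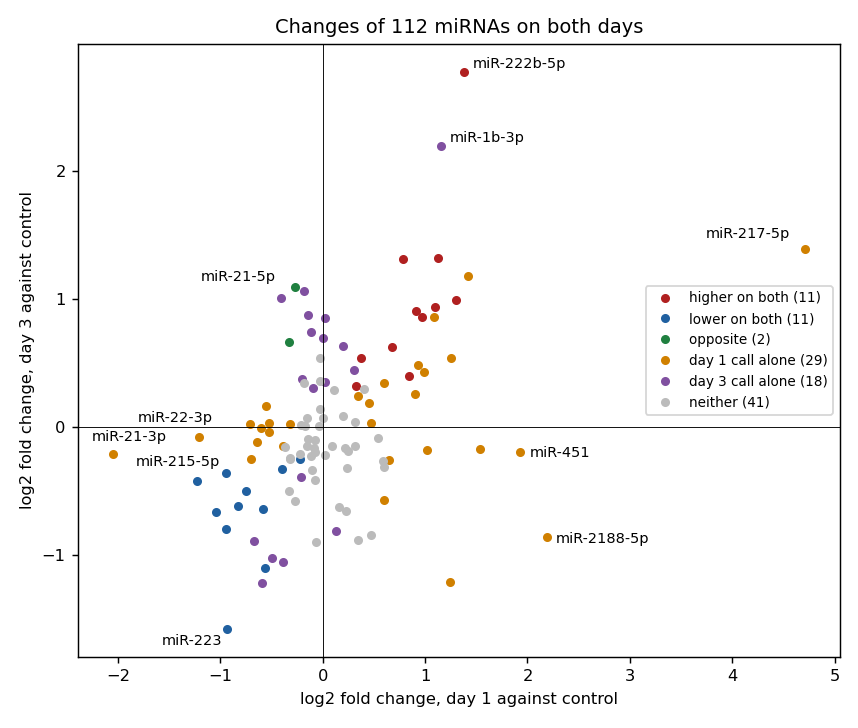
Log2 fold change of each of 112 miRNAs at day 1 (horizontal axis) and day 3 (vertical axis) against the same 3 controls. Colours give the calls by edgeR, with 11 miRNAs higher on both days, 11 lower on both, 2 opposite, 29 called at day 1 alone and 18 at day 3 alone. A call on 1 day alone does not show a difference between the days. With total counts 28 were higher on both days, miR-21-5p and miR-100-5p among them, and 2 were lower on both.

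Positions of miRNAs with large changes were taken from the galGal4 coordinates of the authors' deposited tables. miR-215-5p (chromosome 3, 18143714 to 18143734, plus strand) and miR-194 (18143396 to 18143417) lay together, within the span of IARS2 in the GRCg7b annotation. miR-451 (chromosome 19, 5862908 to 5862930, minus strand) and miR-144-3p (5863045 to 5863066) also lay together, outside any named gene. miR-217-5p lay on chromosome 3 (298961 to 298984, minus strand) outside any named gene, miR-22-3p on chromosome 19 (5377528 to 5377549, minus strand) within TLCD2, miR-21-5p on chromosome 19 (7367282 to 7367303, plus strand) within RPS6KB1, and miR-7446-3p on chromosome 1 (87937436 to 87937453, minus strand) within ABHD10. miR-222a (chromosome 1, 109977233 to 109977256, plus strand) and miR-221-3p (109977744 to 109977766) were neighbours. Exons and introns were not examined. By name, miR-222b-5p matched 2 GRCg7b genes, miR-7 matched 3 and miR-9-5p matched 4, and sequences were not compared. The authors' deposited tables give 1 position for each, on chromosomes 4, Z and 28. Whether their counts come from a single gene was therefore not settled.

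The authors' deposited tables compared each day with the controls. The authors' deposited table for day 1 had 44 features at an adjusted p under 0.05, of which 32 were chicken miRNAs (10 higher, 22 lower) and 12 were small nucleolar RNAs (snoRNAs; 9 higher, 3 lower). The authors' deposited table for day 3 had 28, of which 21 were miRNAs (9 higher, 12 lower) and 7 snoRNAs (4 higher, 3 lower). Of 110 miRNAs present in both tests, 30 of the authors' day 1 calls and 20 of the authors' day 3 calls were shared with the calls made here, all with the same sign. The fold changes correlated across miRNAs with Spearman's rho of 0.995 and 0.985, and their median was higher here by 0.18 and 0.07 on the log2 scale. The authors' size factors used all features, snoRNAs included, while the scaling here used miRNAs alone. In the joint fit with the snoRNA and snRNA reads the miRNA values moved by a median of −0.15 and −0.08. The numbers of higher and lower calls are therefore not on the same scaling. In the authors' deposited table for day 1 the miRNAs with the smallest adjusted p were miR-7446-3p (log2 −1.39), miR-22-3p (−1.37), miR-215-5p (−1.12), miR-140-3p (−0.89), miR-200a-3p (−0.93), miR-146b-5p (−1.10), miR-194 (−0.70), miR-101-3p (−0.78), miR-217-5p (3.10) and miR-451 (1.62). In the authors' deposited table for day 3 they were miR-21-5p (1.00), miR-221-3p (1.19), miR-30a-5p (−1.14), miR-222b-5p (2.11), miR-222a (1.18), miR-146b-5p (−0.85), miR-200a-3p (−0.57), miR-7 (0.76), miR-2954 (0.64) and miR-7446-3p (−0.49).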

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

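The snoRNA comparisons and the tests of other cell types, scaling and sex in this part were chosen after the results were seen. The difference from controls was unequal at day 1 and day 3 for 37 named miRNAs (edgeR, day 3 against day 1, adjusted p under 0.05), 21 of them higher and 16 lower at day 3. The lower ones, as log2 differences, were miR-217-5p (−3.32), miR-2188-5p (−3.05), miR-144-3p (−2.46), miR-451 (−2.13), miR-10a-5p (−1.71), miR-1416-5p (−1.32), miR-181a-3p (−1.23), miR-199-5p (−1.20), miR-106-3p (−1.17), miR-146a-5p (−0.95), miR-6516-3p (−0.92), miR-20b-5p (−0.91), miR-199-3p (−0.86), miR-126-3p (−0.72), let-7i (−0.44) and miR-20a-5p (−0.38). The higher ones were miR-21-3p (1.84), miR-34a-5p (1.42), miR-222b-5p (1.39), miR-21-5p (1.37), miR-9-5p (1.24), miR-22-3p (1.13), miR-1b-3p (1.04), miR-7 (1.02), miR-100-5p (0.99), miR-2954 (0.85), miR-125b-5p (0.83), miR-7446-3p (0.81), miR-215-5p (0.59), miR-27b-3p (0.55), miR-221-3p (0.53), miR-215-3p (0.53), miR-194 (0.48), miR-147 (0.40), miR-26a-5p (0.34), miR-146c-5p (0.33) and miR-200a-3p (0.25). The erythroid and thrombocyte list also differed between the days (camera adjusted p = 0.0249; adjusted p = 0.217 with an estimated correlation). In the snoRNA and snRNA reads, which entered the miRNA fits as alternatives only, 28 features were higher and 7 lower at day 1, and 10 higher and 11 lower at day 3, than in controls, and H/ACA reads per C/D read reached 0.320 at day 1.

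The real grouping was set against other splits of the samples. Each comparison of 3 with 3 samples has 10 splits, too few for a share under 0.05. The real split called 53, 42 and 51 miRNAs for day 1, day 3 and day 3 against day 1, the highest other split called 0 in each, and so 1 of 10 splits reached the real count. Over all 3 groups 1 of 100 splits reached the real count of 74, the highest other being 19. That 1 was the real grouping itself. A split that mixes the groups places their differences within groups, which lowers its count. The splits therefore cannot tell infection from any other difference between the groups.

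The rises of miR-451, miR-144-3p, miR-126-3p and miR-217-5p at day 1 were weighed against RNA of other cells. A lower share of the main cell type would raise the markers of other types alike. The erythroid and thrombocyte sum rose over the stromal sum by 1.85 on the log2 scale (SE 0.219). That stromal sum was mostly miR-100-5p, which fell by 0.33. The median log2 change was 0.75 in the stromal list and 1.26 in the erythroid and thrombocyte list. The ratio of sums thus rests largely on 1 miRNA and does not decide. RNA of blood cells may contribute: miR-223, of white blood cells, fell by 0.94, but its lowest count was 5, so whole blood stays open beside red cells or thrombocytes alone. For miR-217-5p the pancreatic miR-216 miRNAs together had a ratio of 14.7 (exact 95% interval 4.68 to 74.0), in line with pancreatic RNA at day 1, but miR-375 rose by 0.45 only and is also made in gut. Infection and carry-over of tissue at day 1, past a selection of CD3-negative, 28.4-positive cells meant to remove it, therefore cannot be told apart here, and no biological explanation was tested.

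The fall of miR-215-5p and miR-194 at day 1 was weighed against the scaling of the libraries. Over the reported and 5 other scalings the log2 change of miR-215-5p ranged from −1.29 to −0.23 and that of miR-194 from −0.86 to 0.18, and a scaling moves nearly all miRNAs alike. Relative to the median miRNA, which a scaling hardly alters, miR-215-5p changed by −0.92 and miR-194 by −0.50 as reported (SE before the median was subtracted 0.0856 and 0.0946), so both changed unequally to it, and repeating this over scalings adds no support. Whether the amount of either fell cannot be told apart from the scaling. A loss of epithelial cells or a change within them was not tested.

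The rise of miR-2954 at day 3 was weighed against more male birds in that group, since miR-2954 is Z-linked. The W-linked miR-7b had a log2 change of 0.24 (SE 0.129), where more males would lower it. The other 6 Z-linked miRNAs with 1 locus had a median of 0.159, 2 called higher and 0 lower (camera unadjusted p = 0.777). Neither value decides, so sex and infection cannot be told apart for this miRNA.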

How the results depend on the processing

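The alternatives with snoRNA reads, without the epithelial list and with an enlarged inflammatory list were chosen after seeing the data. Called counts were within 1.5 times the reported ones in 22 of 23 alternatives at day 1, 20 of 23 at day 3, 21 of 23 for day 3 against day 1 and 21 of 22 over all groups, with ranges of 34 to 77, 25 to 52, 28 to 83 and 46 to 94. The exceptions were the stricter filter (34, 25, 28 and 46, with fewer miRNAs tested), thinning to the smallest library (27 at day 3), total counts (83 for day 3 against day 1) and leaving out day 3 replicate 1 (27 at day 3). Similar counts did not always mean the same miRNAs. At day 1 total counts shared 39 of the 53 reported calls and turned the direction of 14. Scaling to the snoRNA reads also shared 39 and turned 1. For day 3 against day 1 total counts shared 33 of 51 and turned 13. Leaving out 1 sample gave 44 to 54, 27 to 43, 41 to 54 and 64 to 73. Of the named and called miRNAs 28 of 37, 18 of 34 and 24 of 37 were called in every leave-out. At day 1 let-7f-5p was lost without control 3, miR-99a-5p without control 3 or day 1 replicate 2, and miR-17-3p, miR-30d, miR-100-5p, miR-26a-5p and miR-6601-3p without any 1 of several samples. At day 3 leaving out replicate 1 ended the calls of miR-122-5p, miR-146c-5p, miR-221-5p and miR-9-5p, among others, and leaving out control 3 those of miR-3607-3p, miR-32-5p and miR-99a-5p, among others. For day 3 against day 1 miR-215-3p was lost without day 1 replicate 1, miR-199-5p without day 1 replicate 1 or day 3 replicate 1, and miR-1b-3p without day 1 replicate 3 or day 3 replicate 1, among 13 lost. With replicate number as a block 54, 46 and 52 were called, and correlations of same-numbered samples (−0.0440 to 0.182) overlapped those of others (−0.238 to 0.137), with 6 of 9 samples closest to their own number. Each sample had more differently numbered than same-numbered partners to choose from, so a weak pairing by number stays open.

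Directions that turned did so by the scaling itself, which moves all miRNAs of a library together. At day 1 with total counts the log2 values were miR-100-5p 0.38, miR-101-3p 0.10, miR-142-3p 0.62, miR-147 0.62, miR-148a-3p 0.64, miR-1692 0.0044, miR-194 0.18, miR-19b-3p 0.61, miR-200b-3p 0.68, miR-21-5p 0.44, miR-215-3p 0.061, miR-26a-5p 0.40, miR-27b-3p 0.19, miR-30d 0.49 and miR-92-3p 0.61, and with snoRNA scaling let-7f-5p −0.017 and miR-146c-5p −0.31. For day 3 against day 1 with total counts they were let-7g-5p −0.43, the let-7j-5p and let-7a-5p entry −0.46, miR-142-5p −0.39, miR-146b-5p −0.45, miR-146c-5p −0.27, miR-147 −0.19, miR-194 −0.11, miR-200a-3p −0.34, miR-200b-3p −0.55, miR-215-3p −0.067, miR-215-5p −0.0080, miR-221-3p −0.065, miR-26a-5p −0.26 and miR-27b-3p −0.039. A direction was scored only where the reported or the alternative fit called it.

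Lists called at day 1 were 8 with fry, 2 with RLE scaling, 1 with total counts, 7 without a low-count filter and 0 to 3 leaving out 1 sample. At day 3 they were 4 with fry, 5 without a filter, 0 in every leave-out and 1 with miR-222a and miR-222b added to the inflammatory list. For day 3 against day 1 they were 0 with an estimated correlation, 7 with fry, 0 with total counts, 6 without a filter and 1 to 3 leaving out 1 sample. The cause was not tested. With TMM scaling the log2 change of a list's summed share at day 1 was −0.22 (lymphocyte and natural killer cell), −0.25 (inflammatory response), −0.27 (linked to IBDV), −0.14 (myeloid) and −0.10 (smooth muscle and stroma), and that of the erythroid and thrombocyte list at day 3 was −0.067. Without TMM scaling the erythroid and thrombocyte value at day 3 was 0.051. For that unscaled value leaving out 1 sample gave −0.093 to 0.27, negative without control 2, control 3, day 3 replicate 2 or day 3 replicate 3.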

Other observations

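All tests in this part were chosen after the results were seen. The recovered reads held snoRNAs, which guide modification of ribosomal and spliceosomal RNA. Fitted with the miRNAs in edgeR, 35 of 104 tested snoRNAs and snRNAs differed at day 1 (28 higher, 7 lower), 21 at day 3 (10 higher, 11 lower) and 47 between the days (17 higher and 30 lower at day 3). At day 1 SNORD101 rose by 1.42 on the log2 scale (SE 0.166, adjusted p = 4.78e-13), SNORA75 by 1.43 (SE 0.268), SNORA41 by 0.98 (SE 0.137) and SNORD97 by 0.75 (SE 0.124), while SCARNA14 fell by 1.78 (SE 0.349) and SCARNA13 by 1.07 (SE 0.235). At day 3 SNORD101 was higher (1.14, SE 0.165), snoU83B rose by 1.24 (SE 0.186), and SNORD37 fell by 0.89 (SE 0.112) and SNORD127 by 0.53 (SE 0.109). Of the tested miRNAs 4 were named as snoRNA genes in GRCg7b. Among them miR-1434, at the SNORD37 gene and singled out after its values were seen, had a log2 change of 0.54 at day 3 (SE 0.161, adjusted p = 0.00637) in the same joint fit in which SNORD37 fell. U12, an RNA of the minor spliceosome, rose by 0.78 at day 1 (SE 0.198) and was lower at day 3 than at day 1 (−1.36, SE 0.199). miRNA reads per snoRNA or snRNA read were 40.2 ± 4.98 in controls and 19.4 ± 0.741 at day 1 (SD, n = 3), and between 34.85 and 35.1 in the 3 samples of day 3 (exact permutation p = 0.0143, adjusted p = 0.0286).

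H/ACA snoRNAs, which guide pseudouridylation, and C/D snoRNAs, which guide methylation, were compared. H/ACA reads per C/D read were 0.290 ± 0.00217 in controls, 0.320 ± 0.00544 at day 1 and 0.271 ± 0.00501 at day 3 (SD, n = 3; exact permutation p = 0.00357, the smallest possible). Without the most abundant member of each class the ratios were 0.329, 0.341 and 0.287 (exact permutation p = 0.00357, again the smallest possible). The difference between control and day 1 was then smaller and that between control and day 3 larger. Whether the classes shifted as a whole stays open. Of 48 H/ACA snoRNAs 13 were higher and 2 lower at day 1, 0 and 6 at day 3, and 2 higher and 18 lower at day 3 than at day 1 (camera adjusted p = 0.0857, 0.193 and 0.00522; the last with an estimated correlation adjusted p = 0.0454). Of 38 C/D snoRNAs 8 were higher and 2 lower at day 1, 7 and 3 at day 3, and 10 and 8 between the days (camera adjusted p = 0.193, 0.118 and 0.860).

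miRNAs within 10 kb of each other (43 pairs of 36 miRNAs) changed more alike than pairs shuffled within 4 bins of abundance (10000 shuffles). The median difference in log2 fold change was 0.328 against 0.603 at day 1, 0.309 against 0.548 at day 3 and 0.262 against 0.574 between the days, with a highest adjusted permutation p of 0.0336, though only 26, 32 and 35 of the pairs changed in the same direction. Of the pairs 20 came from the miR-17-92 locus and 1 lay on opposite strands. For pairs on 1 strand without that locus (21 pairs) the adjusted permutation p was 0.0341, 0.0664 and 0.0137, and with 1 value for each of 10 clusters 0.0137, 0.0226 and 0.0137, so shared transcription stays open. For the 2 arms of 1 hairpin, which come from the same precursor (12 pairs), the highest adjusted permutation p was 0.414 and the lowest 0.0666, so a closer change of arms than of shuffled pairs was not shown, and processing, stability and noise at low counts were not separated. The arms of miR-21 had log2 changes of −2.05 (miR-21-3p) and −0.28 (miR-21-5p) at day 1 and −0.21 and 1.09 at day 3, and those of miR-142 −0.82 (miR-142-5p) and −0.08 (miR-142-3p) at day 1.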
